A study of Mus musculus with 8 samples.

How the data were processed

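RNA sequencing was performed on total RNA from the stomachs of wild-type female C57BL/6J mice, an inbred laboratory strain, collected 3 days after adrenalectomy or after a sham operation. Adrenalectomy is the surgical removal of the adrenal glands, which make glucocorticoids, aldosterone and adrenaline, and a sham operation is the same surgery without the removal. Each group held 4 samples. Per the labels' protocols, RNA was extracted with Trizol, purified on columns, made into libraries with an Illumina TruSeq kit, pooled and sequenced on a NextSeq500 instrument. The labels do not say that the samples came from separate animals, so the p-values measure the spread between these samples.

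Per the submitters' processing notes, the authors used Trim Galore, STAR, featureCounts and DESeq2, without versions, and the mouse genome build mm9. The order and settings of these tools, the gene annotation, the strand setting and any filter are not given in the sources used here. The authors deposited 1 table of log2 values, normalized between samples, with 1 column per sample and 24507 rows named by gene symbol. The transformation is not named. In the deposited log2 values the spread between samples shrank for genes of low value, as it does after a regularized log transformation. The median SD over the 8 samples was 0.024 for the 510 tested genes with a mean log2 value up to 4 and 0.089 for the 3172 genes between 8 and 10. Log2 differences are therefore given on this deposited scale, and those of low genes understate the change. The table holds no counts, so the sequencing depth of each sample is unknown and no counting interval was computed. Reads of overlapping or antisense genes cannot be told apart without the strand setting.

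The 8 columns of this series' samples were used, and 8 further columns with other sample names were not analysed here. A total of 26 rows whose gene names had been turned into dates were left out. Genes entered the tests when the mean of their linear values over the 8 samples was at least 10, which kept 16889 genes and left out 7592. Groups were compared with limma 3.58.1 in R 4.3.3, with an intensity trend in the moderated variance and group as the only term. P-values are two-sided and were adjusted with the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. A log2 difference is adrenalectomy minus sham, with the standard error of that fit. Values given for a group are the mean ± SD of 4 samples.

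A set of 42 gene lists for pathways, cell types, neighbouring tissues and quality was fixed before the data were examined. The lists covered glucocorticoid-induced genes, steroid receptors, the clock, sodium transport, the gastric epithelial lineages, proliferation, cytokines, interferon responses, antigen presentation, leukocyte classes, stroma, nerves and vessels, squamous epithelium, pancreas, intestine, liver, fat, blood, skeletal muscle, metabolism, protein folding stress, immediate early genes, respiration, ribosomes and reference genes. The 15 mitochondrially encoded genes had no measured member, so 41 lists were tested with camera in limma, a competitive test, at a preset inter-gene correlation of 0.01 and with adjustment over the 41 lists. The same test with an estimated correlation and fry, a rotation test of whether the genes of a list move on balance in 1 direction, were run beside it. A list score is the mean log2 value of the measured members in a sample.

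The rule for named genes was also fixed before the data were examined. It takes the 10 largest increases and the 10 largest decreases among genes past the threshold whose groups did not overlap, leaving out predicted genes and antigen receptor segments, up to 4 members with the smallest p of each list described, and a set of steroid targets, gastric lineage markers and inflammatory genes named in advance. Ifng, Il6 and Cd3e, of that set, were below the filter on low values and were not tested. A few genes that the rule takes are not reported here. Genes named outside the rule are marked as chosen after their values were seen.

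The code was tested on simulated data of 16889 genes with the mean and residual spread of the real genes and 200 changed genes. Of 50 genes changed at each size, it recovered 54% at a log2 change of 0.25, 90% at 0.5, 96% at 1 and 100% at 2. It called 182 genes, of which 12 were unchanged, and of the lists it called the 1 that had been shifted. The noise was drawn independently for each gene, whereas members of the real lists can move together. The estimated correlation was 0.93 for the real skeletal muscle genes. The simulation therefore does not show how often camera calls unshifted lists in the real data. Symbols were matched to the GENCODE M21 annotation, 23820 directly and 289 through a synonym, for transcript length and GC content only. Because that annotation is on GRCm38 and not on the authors' build, no coordinates are given, and the order of genes was taken from the GRCm38.p6 assembly. Alternatives covered the log scale, the filter, the normalization, the variance model, a block for the replicate number, the set test and leaving out each sample. Covariates for RNA of neighbouring tissues and of the antrum, a fit without 3 samples and a correction for transcript length and GC content were added after the data had been seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.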

Results

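Stomach samples of mice, 4 taken 3 days after adrenalectomy and 4 taken 3 days after a sham operation, were profiled by RNA sequencing, to compare gene expression in the stomach with and without the adrenal glands, in a study of glucocorticoids and gastric inflammation. The most abundant transcript was Pgc, which encodes the pepsinogen of chief cells, with a mean of 10.8% of the summed linear values, followed by Gkn1 at 3.23% and Gkn2 at 2.48%, which encode secreted proteins of the gastric surface. Gkn2 is outside the rule for named genes and was chosen after its values were seen. The 10 most abundant genes took 22.4% to 27.2% of the sum in each sample. Sequencing depth is unknown, since the deposited table holds normalized log2 values and no counts.

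Expression differed between the groups for 289 of 16889 tested genes, of which 157 were higher and 132 lower after adrenalectomy. Most changes were small, with a median absolute log2 difference of 0.26. The changes reached 2-fold in 5 genes. Mcpt1, a mast cell protease, rose 2.24-fold (log2 difference 1.16 ± 0.20 SE, adjusted p = 0.0393), and Atp6v0d2, a subunit of the vacuolar proton pump, rose 2.02-fold (1.01 ± 0.14 SE, adjusted p = 0.0239). The lipocalin gene Obp2a fell by 1.10 ± 0.19 SE on the log2 scale (adjusted p = 0.0398), the clock gene Per1 fell by 1.04 ± 0.07 SE (adjusted p = 0.00500) and Fkbp5, which encodes a co-chaperone that restrains the glucocorticoid receptor, fell by 1.03 ± 0.19 SE (adjusted p = 0.0431).

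Other large increases were in the collagen gene Col6a5 (log2 difference 0.98), Bpifb1 (0.96), the phospholipase gene Pla2g4c (0.84), the gasdermin genes Gsdmc2 (0.83) and Gsdmc3 (0.76), the antiviral genes Oas1g (0.83) and Oas1a (0.76), and the apelin receptor gene Aplnr (0.75). Gsdmc2 stood at a log2 value of 12.27 ± 0.12 (SD, n = 4) in sham samples and 13.10 ± 0.09 (SD, n = 4) after adrenalectomy. The Gsdmc and Oas1 genes are close paralogs, so how their reads were divided is uncertain. Other large decreases were in Pdk4, a kinase that limits entry of pyruvate into the citric acid cycle (-0.85), the fucosyltransferase gene Fut4 (-0.81), Cilp (-0.75), Klf9 (-0.68), the glycosyltransferase gene B4galnt2 (-0.65), Fam13a (-0.64) and the guanine deaminase gene Gda (-0.58). The 4 samples of each group did not overlap for any of the 289 genes. Groups did not overlap for 2100 genes, 12.4% of those tested, against 2.86% by chance.

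**Figure D1:**
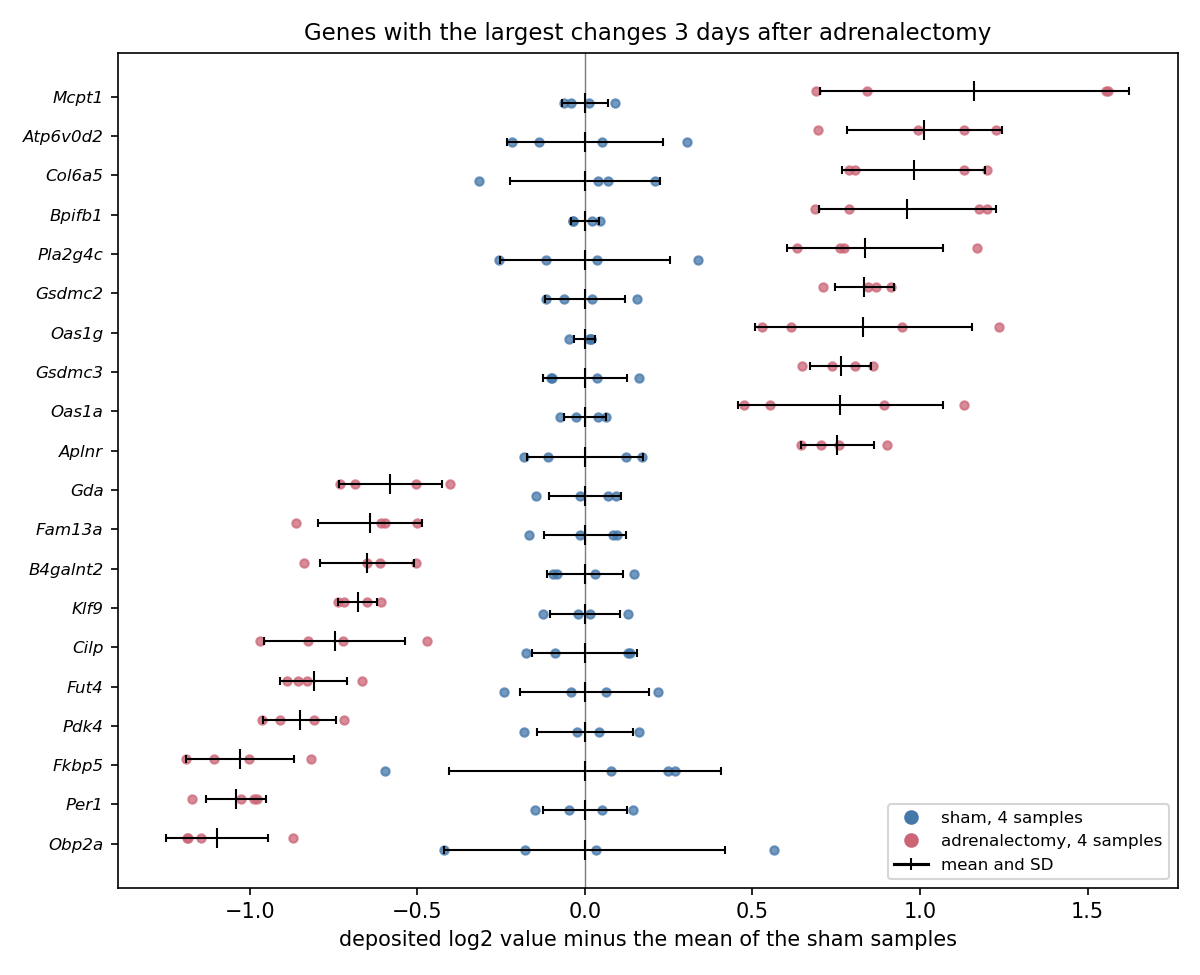
Deposited log2 values of the genes with the 10 largest increases and the 10 largest decreases under the rule for named genes, relative to the mean of the sham samples (horizontal axis, log2 units). There is 1 point per sample, with bars for the mean and SD of 4 samples. The groups do not overlap for any gene shown, from Obp2a at -1.10 to Mcpt1 at 1.16.

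The number of called genes moved by over 1.5 times with any single sample left out, to 633 without sham replicate 1, 58 without sham replicate 2, 27 without sham replicate 3 and 50 without sham replicate 4, and to 86, 51, 55 and 53 without adrenalectomy replicates 1, 2, 3 and 4. With adrenalectomy replicate 1 and sham replicates 2 and 3 left out together, and with scores of squamous and skeletal muscle RNA as a covariate, both chosen after the data had been seen, limma called 0 genes, with 1822 and 2301 genes at an unadjusted p under 0.05 against 3245 in the full data. The 289 genes kept their direction in each of these settings. Where samples were left out this had to follow, since the groups did not overlap for any of the 289. The 43 called genes among those named by the rule kept their call in 6 to 22 of 24 alternative settings. The 132 lower genes had long transcripts, with a median of 4902.5 bases against 3191 for tested genes that were not called.

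Several glucocorticoid-induced genes fell. Of 38 measured members of the list, 8 fell and none rose over all genes tested, and 16 fell adjusted over the list alone. The median log2 difference was -0.22, and -0.12 for the glucocorticoid-induced genes with the squamous and skeletal muscle score as a covariate. Besides Per1, Klf9, Pdk4 and Fkbp5, the list held Fam107a, which went from 7.47 ± 0.08 (SD, n = 4) to 7.09 ± 0.03 (SD, n = 4; adjusted p = 0.0155). The other falling members, Cebpd, Foxo3 and Glul, with log2 differences of -0.43, -0.29 and -0.21, were outside the rule for named genes and were named after their values were seen. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, differed by -0.24 (adjusted p = 0.102) and Zbtb16 by -0.42 (adjusted p = 0.398), so neither passed. The mean log2 value of the list was 10.89 ± 0.10 in sham samples and 10.69 ± 0.12 after adrenalectomy (SD, n = 4 each), and the groups overlapped. The overlap came from adrenalectomy replicate 1, the sample with most liver RNA, at 10.86. The other adrenalectomy samples stood at 10.59 to 10.67 and the sham samples at 10.74 to 10.99. The list passed camera with an adjusted p of 5.99e-08, but not with an estimated correlation (adjusted p = 0.224). Fkbp5 was called in 11 of 24 alternative settings and Per1 in 22.

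Among steroid receptors and steroid-activating enzymes, 2 of 11 measured members rose, Fkbp4 (0.20 ± 0.03 SE) and Hsp90aa1 (0.16 ± 0.03 SE), both chaperones of steroid receptors and of many other proteins. The glucocorticoid receptor gene Nr3c1 differed by 0.09 (adjusted p = 0.165), Star by -0.19 (adjusted p = 0.180) and Hsd11b1, which regenerates active glucocorticoid, by 0.35 ± 0.57 SE (adjusted p = 0.769). Hsd11b1 stood at 10.27 in adrenalectomy replicate 1, the sample with most liver RNA, and at 7.40 to 8.03 in the other adrenalectomy samples, and its log2 difference was -0.29 without that sample and -0.44 with the liver score as a covariate. The list passed camera with an adjusted p of 0.0411, not with an estimated correlation (adjusted p = 0.243) and in 15 of 24 alternatives. The score of the list was 9.88 in adrenalectomy replicate 1 and 9.54 to 9.60 in the other adrenalectomy samples, and without that sample the median of the steroid receptors and steroid-activating enzymes fell from 0.13 to 0.07 and the camera call was lost (adjusted p = 0.0916, in a range of 0.00847 to 0.157 over the alternatives).

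Several antigen presentation genes rose. Of 23 measured members, 10 rose over all genes tested and 17 rose adjusted over the list alone, and the median log2 difference was 0.33. Cd74, the invariant chain of class II molecules, rose 1.59-fold, from 12.55 ± 0.07 (SD, n = 4) to 13.22 ± 0.13 (SD, n = 4; adjusted p = 0.00825). The class II genes H2-Ab1 and H2-Aa rose by log2 differences of 0.58 and 0.55, and Ciita, the master regulator of class II genes, by 0.33 (adjusted p = 0.0150). The mean log2 value of the list was 9.39 ± 0.011 in sham samples and 9.68 ± 0.064 after adrenalectomy (SD, n = 4 each). Camera gave an adjusted p of 8.27e-16, and the call was lost with an estimated correlation (adjusted p = 0.169).

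Interferon-stimulated genes lay higher as a group. All 34 type I interferon response genes had a higher mean after adrenalectomy, with a median log2 difference of 0.47. Oas1g and Oas1a rose over all genes tested, and 28 rose adjusted over the list alone. Irf9, part of the interferon-activated transcription factor, differed by 0.27 (adjusted p = 0.0504) and Bst2, an antiviral membrane protein, by 0.63 (adjusted p = 0.0615). The list score was 10.05 ± 0.029 in sham samples and 10.55 ± 0.30 after adrenalectomy (SD, n = 4 each), and reached 10.95 in adrenalectomy replicate 4 against 10.31 to 10.58 in the other adrenalectomy samples. Without that sample the median of the type I interferon response genes was 0.29. Of 33 interferon-gamma response genes, Ciita and Socs1, a feedback inhibitor of cytokine signalling (0.20, adjusted p = 0.0398), rose, 23 rose adjusted over the list alone, and the median was 0.26. Irgm2 differed by 0.48 (adjusted p = 0.0547) and the immunoproteasome gene Psmb8 by 0.42 (adjusted p = 0.0566). Camera gave adjusted p-values of 2.27e-16 and 3.30e-13, and both calls were lost with an estimated correlation (adjusted p = 0.343 and 0.243).

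Macrophage and monocyte markers rose in 6 of 31 measured members and in 18 adjusted over the list alone, where 1 member also fell, with a median log2 difference of 0.23. Adgre1, which encodes the macrophage antigen F4/80, rose by 0.36 ± 0.04 SE (adjusted p = 0.0161), the receptor gene Csf1r by 0.52 ± 0.07 SE (adjusted p = 0.0223), Retnla by 0.31 (adjusted p = 0.0224) and the complement gene C1qc by 0.38 (adjusted p = 0.0317). The camera adjusted p was 4.91e-10, and 0.243 with an estimated correlation. Dendritic cell markers, with 16 measured, had a median of 0.08 and no called gene. Itgax differed by 0.30 (adjusted p = 0.0611), Irf8 by 0.19 (adjusted p = 0.169) and Xcr1 by 0.12 (adjusted p = 0.197), and the list passed camera (adjusted p = 0.000660) but not with an estimated correlation (adjusted p = 0.402). All 12 measured B cell and plasma cell markers had higher means, with a median of 0.09, none called over all genes and 7 adjusted over the list alone. Bank1 differed by 0.09 (adjusted p = 0.0890), Pou2af1 by 0.13 (adjusted p = 0.118) and Xbp1, which many secretory cells express, by 0.13 (adjusted p = 0.0597). The list passed camera (adjusted p = 1.24e-05) but not with an estimated correlation (adjusted p = 0.169), and the call ended under a filter at a mean of 100.

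Cytokine and chemokine genes differed by small amounts on the deposited scale, which understates changes in genes of low value. Sham means were 4.40 for Tnf and 6.52 for Il1b, against 13.35 for Il18. Of the 47 genes in the list, 33 were measured. Of 33 measured cytokine and chemokine genes, Il33, an epithelial and stromal alarmin, rose over all genes tested, from 13.30 ± 0.19 (SD, n = 4) to 13.90 ± 0.18 (SD, n = 4; adjusted p = 0.0483), and was called in 6 of 24 alternatives. Adjusted over the list alone, 5 rose and 1 fell, and the median was 0.04, in a range of 0.0086 to 0.093 over the 24 alternatives. Il1b differed by 0.11 (adjusted p = 0.325), Tnf by 0.02 (adjusted p = 0.612), Ccl2 by 0.12 (adjusted p = 0.210), Ccl12 by 0.14 (adjusted p = 0.0611), Cxcl10 by 0.14 (adjusted p = 0.134), Nos2 by 0.15 (adjusted p = 0.0841) and Il18 by -0.18 (adjusted p = 0.119). The list passed camera (adjusted p = 0.00648) but not with an estimated correlation (adjusted p = 0.169) or under a filter at a mean of 100. Neutrophil markers did not pass (median -0.03, adjusted p = 0.870), and S100a8, at a low sham mean of 4.01, differed by -0.01.

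Of 25 measured unfolded protein and integrated stress response genes, 5 rose over all genes tested and 14 adjusted over the list alone, with a median log2 difference of 0.13. Hyou1 rose by 0.38 ± 0.04 SE (adjusted p = 0.00825), Sdf2l1 by 0.42 ± 0.06 SE (adjusted p = 0.0223), Creld2 by 0.44 ± 0.07 SE (adjusted p = 0.0288) and Hspa5, which encodes the chaperone BiP, by 0.35 ± 0.06 SE (adjusted p = 0.0361). The camera adjusted p was 6.91e-09, and 0.169 with an estimated correlation. Proliferation genes had higher means in 33 of 34 members with a median of 0.14, and none was called, over all genes or adjusted over the list alone. Mki67 differed by 0.17 (adjusted p = 0.112), Mcm2 by 0.34 (adjusted p = 0.0834), Mcm4 by 0.31 (adjusted p = 0.104) and Mcm5 by 0.41 (adjusted p = 0.108). That list passed camera (adjusted p = 5.34e-09) but not with an estimated correlation (adjusted p = 0.443), and the median of the proliferation genes was 0.09 with the squamous and skeletal muscle score as a covariate.

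**Figure D2:**
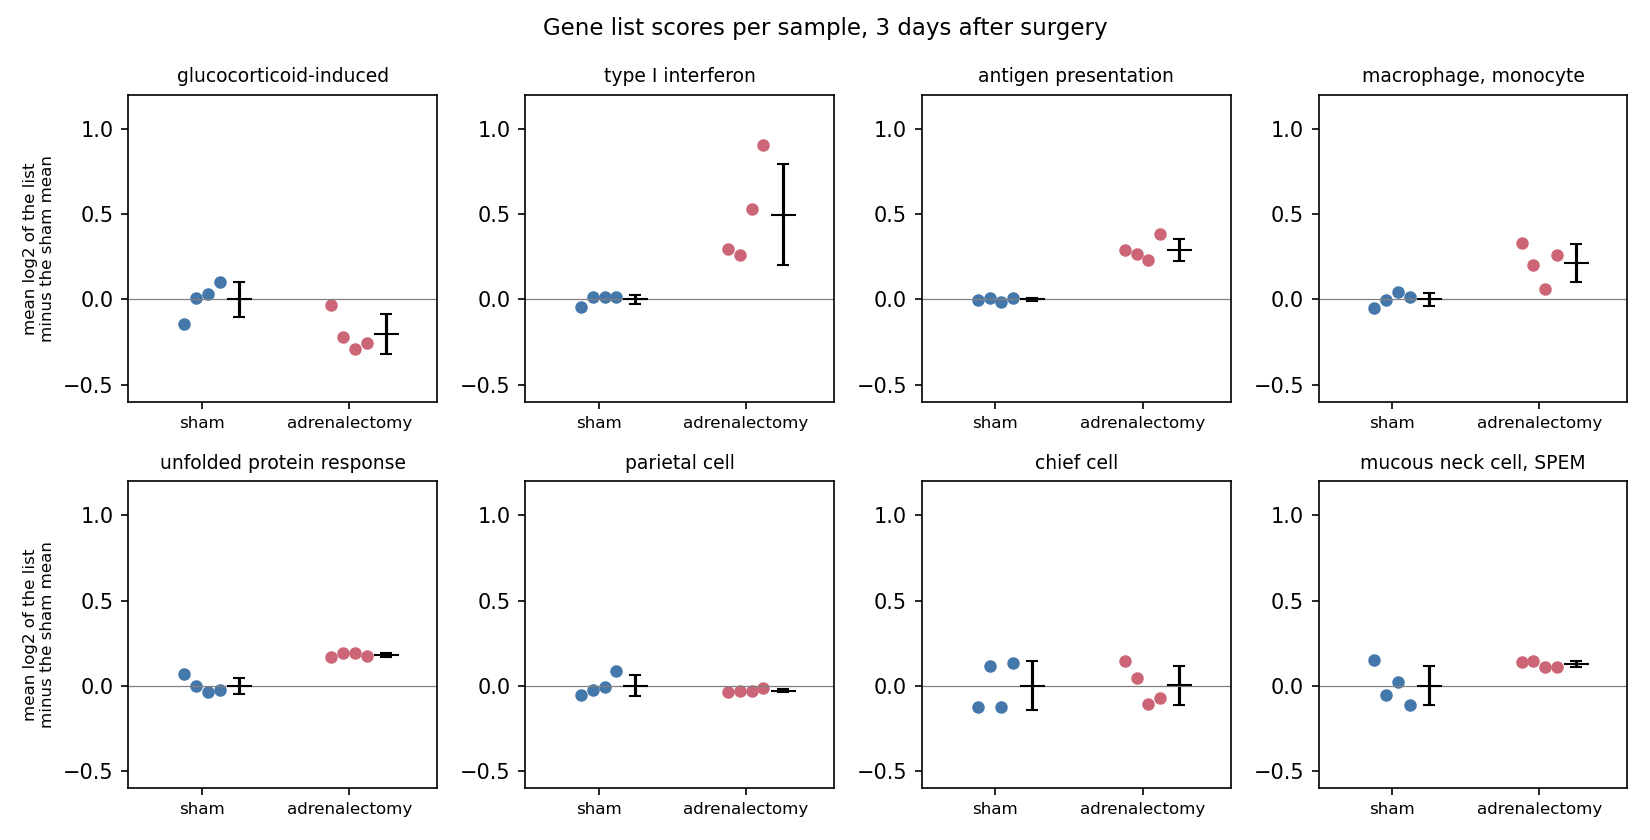
Mean log2 value of the measured members of 8 gene lists in each sample, relative to the mean of the sham samples (vertical axis, log2 units), with 1 point per sample and bars for the mean and SD of 4 samples per group. The antigen presentation scores of the groups do not overlap, with a difference of 0.29, and the chief cell scores do, with a difference of 0.0034.

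Few markers of the gastric epithelial lineages were called. None of 20 parietal cell markers was called, with a median of -0.01 (camera adjusted p = 0.288). Atp4a and Atp4b, which encode the proton pump, differed by -0.09 ± 0.09 SE and 0.01 ± 0.06 SE, Aqp4 by -0.24 (adjusted p = 0.0606), Kcnj16 by -0.10 (adjusted p = 0.144), Kcne2 by 0.12 (adjusted p = 0.288) and Vegfb by 0.12. None of 14 chief cell markers was called (median 0.02, camera adjusted p = 0.921), although 2 rose and 2 fell adjusted over the list alone and fry found change in either direction (adjusted p = 0.000145). Pga5 differed by 0.78 (adjusted p = 0.0845), Chia1 by -0.80 (adjusted p = 0.141), Cym by -0.60 (adjusted p = 0.0613), Gif by -0.03, Pgc by -0.16 and Bhlha15, which encodes the chief cell transcription factor Mist1, by 0.07. Of 27 markers of mucous neck cells and of spasmolytic polypeptide-expressing metaplasia, a mucous cell state of the injured stomach, Bpifb1 rose 1.95-fold (adjusted p = 0.0150) and the list did not pass (median 0.08, adjusted p = 0.0748). Adjusted over the list alone, 3 of these markers rose and 1 fell, and fry found change in either direction (adjusted p = 4.90e-08), the smallest such p of the 41 lists. In all, 26 of the 41 lists passed that test of either direction, housekeeping genes among them. Camera called the mucous neck cell and SPEM markers, with SPEM short for that metaplasia, in 4 of 24 alternatives, without sham replicate 1 (adjusted p = 0.00705), without sham replicate 3 (adjusted p = 0.0370), and with the liver or antral score as a covariate (adjusted p = 0.0196 and 0.0355). Tff2 differed by 0.02, Muc6 by 0.35, Wfdc2 by 0.17, Cftr by -0.04, Gkn3 by 0.41, Cd44 by -0.18 and Clu by 0.23 (adjusted p = 0.0539), Lyz2 by 0.29 (adjusted p = 0.0837) and Slc7a11 by -0.35 (adjusted p = 0.0847). Of 15 surface mucous cell markers, Muc1 rose by 0.14 (adjusted p = 0.0393), Muc5ac differed by -0.12, Gkn1 by 0.05, Tff1 by 0.00033, Aldh3a1 by -0.17, Capn9 by 0.17 and Car9 by 0.08, and the list did not pass (adjusted p = 0.541). Tuft cell markers, of chemosensory cells, had a median of 0.18 in 13 members and no called gene. Alox5ap differed by 0.23 (adjusted p = 0.0884), Dclk1 by 0.22 (adjusted p = 0.176), Rgs13 by 0.20 (adjusted p = 0.201) and Siglecf by 0.24 (adjusted p = 0.203). They passed camera (adjusted p = 0.000535) but not with an estimated correlation (adjusted p = 0.429).

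Smooth muscle genes fell in 3 of 20 members and in 8 adjusted over the list alone, with a median log2 difference of -0.16. Tpm2, Tagln and Myh11, of the contractile apparatus, fell by 0.19, 0.20 and 0.27 (adjusted p = 0.0250, 0.0393 and 0.0476), and Des differed by -0.21 (adjusted p = 0.0803). The list passed camera (adjusted p = 1.38e-07) but not with an estimated correlation (adjusted p = 0.333), and without adrenalectomy replicate 1 and sham replicates 2 and 3 its median was -0.05. Among 27 fatty acid oxidation and fasting genes, Pdk4 and Hadhb fell (Hadhb by 0.13, adjusted p = 0.0479), Cpt1a differed by -0.15 (adjusted p = 0.0928) and Cd36 by -0.27 (adjusted p = 0.0944). The median was -0.04, and the camera call (adjusted p = 0.0235) held in 20 of 24 alternatives and was lost with an estimated correlation (adjusted p = 0.596). The score of the list was 11.30 in adrenalectomy replicate 1, the sample with most liver RNA, and 10.79 to 10.88 in the other adrenalectomy samples. The median was -0.11 without that sample and -0.12 without it and sham replicates 2 and 3. The call was lost without sham replicate 4 and without adrenalectomy replicate 2, 3 or 4, with adjusted p-values of 0.0532, 0.0667, 0.0758 and 0.0887 for the fatty acid oxidation and fasting genes. Of 30 immediate early genes, Btg2 rose by 0.24 (adjusted p = 0.0126), and Junb, Zfp36 and Gadd45b differed by 0.16, 0.15 and 0.18 (adjusted p = 0.0717, 0.144 and 0.199). That list passed camera (adjusted p = 0.0411) in 16 of 24 alternatives but not with an estimated correlation (adjusted p = 0.679). The median of the immediate early genes was 0.06, and 0.03 without sham replicate 4, 0.11 without adrenalectomy replicate 1 and 0.10 without adrenalectomy replicate 4.

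RNA of neighbouring tissues differed between single samples. The liver score was 13.5 in adrenalectomy replicate 1, where the albumin gene Alb reached a log2 value of 17.7, 10.9 in adrenalectomy replicate 2, 10.8 in sham replicate 4 and 9.71 in adrenalectomy replicate 3, against 8.62 to 8.72 in the other 4 samples. None of the 24 liver genes was called, with log2 differences of 3.27 ± 1.86 SE for Alb, 2.22 ± 1.39 SE for Fga, 2.18 ± 1.25 SE for Ahsg and 1.69 ± 1.05 SE for Hpx. The list passed camera (adjusted p = 0.000861) but not with an estimated correlation (adjusted p = 0.679), and its median fell from 1.56 to 0.57 without adrenalectomy replicate 1, which ended the call. Skeletal muscle genes stood at 9.04 and 9.06 in sham replicates 2 and 3 and at 6.93 to 7.18 in the other 6 samples. Squamous forestomach genes stood at 12.3 in both of those samples and at 10.1 to 11.6 in the rest. Tnnt3 differed by -1.87 ± 0.57 SE, Ckm by -0.67 ± 0.25 SE, Tnni2 by -0.41, Tnni1 by -0.28, Rptn by -1.50 ± 0.57 SE, Dsg1a by -1.02, Sprr1b by -0.68 and Perp by -0.32, none of them called. The medians of the 2 lists were -1.09 and -0.67 (camera adjusted p = 3.26e-06 and 1.65e-05, and 0.535 and 0.611 with an estimated correlation). Without adrenalectomy replicate 1 and sham replicates 2 and 3 they were -0.05 and -0.17, and neither list passed. Without sham replicate 3 alone the medians were -0.73 for skeletal muscle genes and -0.44 for squamous forestomach genes, and without adrenalectomy replicate 3 the latter was -0.33.

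**Figure D3:**
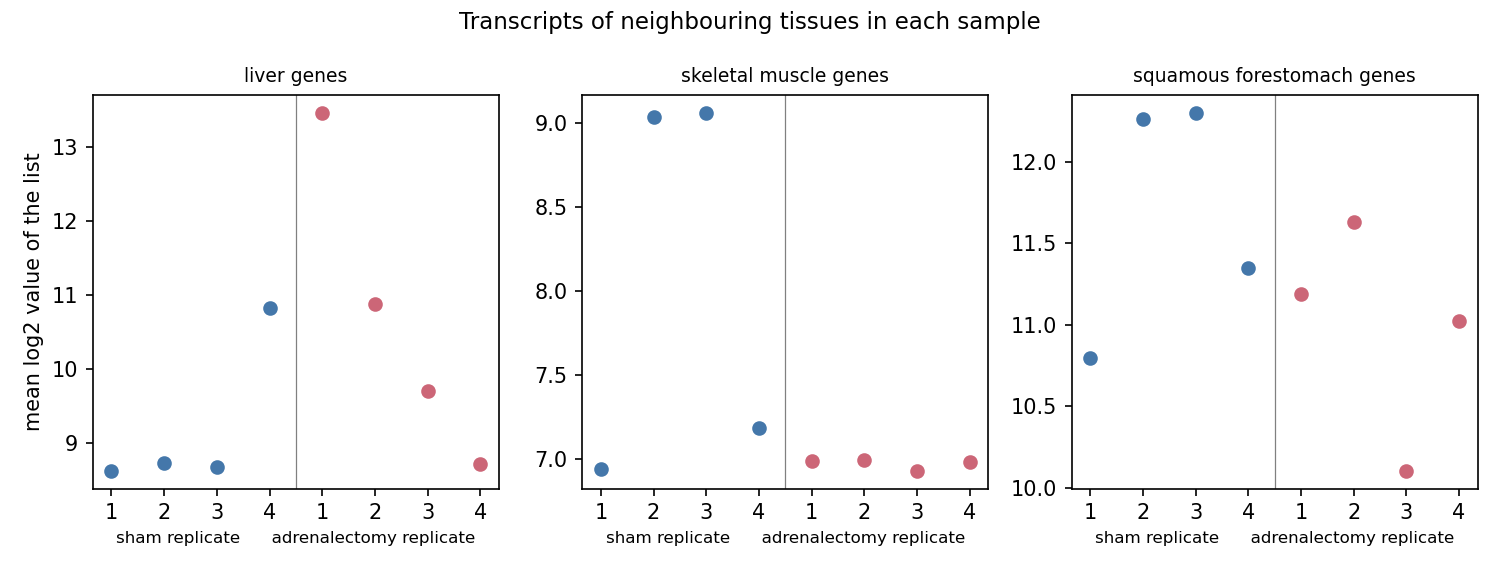
Mean log2 value (vertical axis) of the measured genes of 3 neighbouring-tissue lists in each of the 8 samples (horizontal axis, replicate number within group), with 1 point per sample. The liver score is 13.5 in adrenalectomy replicate 1, and skeletal muscle scores are 9.04 and 9.06 in sham replicates 2 and 3.

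Of the 41 lists, 18 passed camera, 13 of them higher and 5 lower, while none passed with an estimated correlation, 11 passed fry in 1 direction and 26 passed its test of change in either direction. The same test called up to 25 lists in other divisions of the 8 samples into 4 and 4, so its count does not set this comparison apart. The remaining lists did not pass camera. Of all lists that did not, sodium transport genes passed fry in 1 direction (adjusted p = 0.0499), and core clock, sodium transport, chief cell, mucous neck cell, T cell, fibroblast, endothelial, pancreatic, enterocyte, erythroid and housekeeping genes passed its test of change in either direction, with adjusted p-values from 4.90e-08 to 0.0413. Core clock genes had a median of -0.10 (adjusted p = 0.288), and Cry1, named after its values were seen, rose by 0.45 (adjusted p = 0.0487). Sodium transport and aldosterone-responsive genes had a median of -0.05 (adjusted p = 0.0748), eosinophil markers 0.09 (adjusted p = 0.0722), mast cell and basophil markers 0.05 (adjusted p = 0.195), T cell markers 0.03 (adjusted p = 0.0670), cytotoxic and innate lymphocyte markers 0.01 (adjusted p = 0.288), fibroblast and matrix genes 0.03 (adjusted p = 0.168) and endothelial markers 0.02 (adjusted p = 0.340). Medians lay within 0.03 of 0 for enteroendocrine, neuronal, pancreatic acinar, intestinal enterocyte, adipocyte, erythroid, cholesterol synthesis, oxidative phosphorylation, ribosomal protein and housekeeping genes, with camera adjusted p-values from 0.0865 for oxidative phosphorylation to 0.985 for adipocyte genes. Called members were 2 higher and 1 lower among core clock genes, 2 higher among fibroblast genes and 1 higher among mast cell and basophil markers. T cell and housekeeping genes held 1 higher member each, and pancreatic acinar and intestinal enterocyte genes 1 lower member each. The mean of the adipocyte list was 0.11 and its median -0.02, the cholesterol synthesis list had a mean of 0.03 and a median of -0.0028, and the enteroendocrine list had a mean of -0.0040 and a median of 0.00042, each with the 2 signs apart.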

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

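The tests of liver, squamous and muscle RNA were chosen after the results were seen, as was the last condition of the length test. So was the comparison of antral scores with their range in the sham samples. The fits with an antral covariate and with the length and GC trend removed were added after the data had been seen, with their first bounds written before their results were seen, and the splits of the samples were planned. The genes Apoa2, Acta1 and Krt13 are outside the rule for named genes and were chosen after their values were seen.

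Within the 4 samples of a group, 1 sample stood far from the other 3 in 19 of 324 group values of named genes and lists, where chance gives about 16.2. Sham replicate 4 stood high for Ahsg at a log2 value of 11.18 against 8.31 to 8.46 in the other sham samples, for Alb at 14.16 against 8.79 to 9.06, for Fga at 10.19 against 6.99 to 7.01, for the liver list at 10.83 against 8.62 to 8.72 and for Kcne2 at 13.97 against 13.70 to 13.74. It stood low for Oas1g at 10.61 against 10.67 in the others. Sham replicate 1 stood high for Hyou1 at 13.44 against 13.31 to 13.33, Mcm2 at 11.07 against 10.75 to 10.80, Mcm4 at 10.86 against 10.55 to 10.57 and Mcm5 at 10.75 against 10.38 to 10.45, and low for the type I interferon list at 10.01 against 10.06 to 10.07. Sham replicate 2 stood low for the cholesterol and fatty acid synthesis list at 12.73 against 13.04 to 13.09. Adrenalectomy replicate 4 stood low for Dclk1 at 11.32 against 11.49 to 11.51 and Des at 15.35 against 15.51 to 15.54, and high for Lyz2 at 12.32 against 12.08 to 12.11 and Obp2a at 7.76 against 7.44 to 7.48. Adrenalectomy replicate 3 stood low for Cd36 at 13.90 against 13.95 to 13.96, adrenalectomy replicate 2 low for Nr3c1 at 12.96 against 13.00 to 13.01, and adrenalectomy replicate 1 high for the list of steroid receptors and activating enzymes at 9.88 against 9.54 to 9.60.

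Transcripts of liver, skeletal muscle and squamous epithelium stood high in single samples of either group. The liver score of sham replicate 4 exceeded that of adrenalectomy replicate 4 by 2.11, which argues against adrenalectomy alone as the source. These were the highest sham and the lowest adrenalectomy score, compared after the scores were seen. Adrenalectomy replicates 1 to 3 stood above sham replicates 1 to 3, so a part played by adrenalectomy was not excluded. Across the 22 of 24 liver genes with an excess in both, the log10 excess over sham replicates 1 to 3 was correlated between adrenalectomy replicates 1 and 2 (Pearson r = 0.994 across genes, which are not independent replicates). A correlation does not show that the ratio of the excesses was the same for each gene. Liver RNA carried into single samples is a candidate source, with Alb at 17.69, Ahsg at 14.75 and Apoa2 at 13.72 in adrenalectomy replicate 1. Without sham replicates 2 and 3 the median log2 difference was -0.051 for the skeletal muscle list and -0.075 for the squamous list, against -1.09 and -0.67 with them, but these samples were the 2 with the highest scores of both lists, so leaving them out had to shrink the medians and does not bear on where the RNA came from. In them Acta1 stood at 12.65 and 12.55 and Krt13 at 16.26 and 16.15, and the source of the muscle and squamous RNA stays open. In sham replicate 1, 23 of the 24 liver genes had deposited linear values of at least 100, but that scale draws values toward the mean of the gene, so how many of them the stomach itself expresses is not known, and 3 are in another list.

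Antigen presentation and type I interferon genes lay higher after adrenalectomy, with medians of 0.33 and 0.47 in all samples. Medians of 0.324 and 0.558 without adrenalectomy replicate 1 argue against the liver RNA of that sample as the whole cause. Adrenalectomy replicates 2 and 3 stayed in that fit with liver scores of 10.88 and 9.71, so it does not test liver RNA in general. Adrenalectomy replicate 4, with a liver score of 8.72, had the highest list scores, 9.77 and 10.95. Dilution by squamous and muscle RNA is argued against by medians of 0.303 and 0.452 without sham replicates 2 and 3. A differing share of antrum, the distal stomach, scored with Gast, Pdx1 and Nkx6-3, was not tested by the fit with the antral score as a covariate (medians of 0.327 and 0.472), since that score hardly differed between the groups, at 8.19 ± 0.94 in sham samples and 8.17 ± 0.41 after adrenalectomy (SD, n = 4 each). The scores argue against it, since the antral scores after adrenalectomy, 7.75 to 8.62, lay within the sham range of 7.35 to 9.28 while the lowest antigen presentation and interferon scores after adrenalectomy lay 0.223 and 0.246 above the highest sham score, which holds unless antral share acts differently in the 2 groups. That loss of adrenal hormones raised these genes may hold as a hypothesis for the operated group, but more leukocytes and more transcript per cell were not separated, and effects of surgery beyond the loss of hormones, or infection, were not tested.

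The 132 genes lower after adrenalectomy had long transcripts, with a median of 4902.5 bases against 3191 for genes not called (permutation p = 1e-04, the smallest that 10000 draws can give), and a lower GC content of 46.7% against 49.8% (permutation p = 1e-04), while the 157 higher genes had a higher GC content of 52.5% (permutation p = 0.001) and a median of 2923 bases (permutation p = 0.154). The slope of the log2 values per 10-fold length ran from -0.086 in adrenalectomy replicate 1 to 0.046 in sham replicate 1, and the slope per 10 percentage points of GC content was 0.0049 to 0.011 in the adrenalectomy samples and -0.027 to 0.0088 in the sham samples. After the trend with length and GC content was removed from each sample, the median log2 difference of the 132 genes was -0.203 (quartiles -0.31 and -0.12) against -0.229, and 132 of 132 stayed lower, which met the bound set beforehand against the trend as the cause of their decrease. That bound concerned the size of the decrease and not the lengths: only 74 of the 132 stayed past the threshold, and the 80 genes called lower after the removal had a median of 3406.5 bases (permutation p = 0.446), so a condition on length was added after this was seen. Removing a trend itself evens out lengths, so whether a length or GC trend between samples or a change in long genes of low GC content made the pattern cannot be told apart.

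The numbers of called genes were larger in the real division of the samples than in any other. Of the 35 splits of the 8 samples into 4 and 4, only 1, the real one, gave 289 genes or as many as 157 in 1 direction, 132 in the other or 5 at 2-fold, and the highest of the other splits gave 1 gene. With 35 splits no result can be rarer than 1 in 35, and these counts come from 1 fit. Chance is therefore argued against but not excluded. The splits cannot tell adrenalectomy from any other difference between the groups. For the number of called lists they do not argue against chance, since 9 of the 35 splits gave at least the real 18 and the highest of the others gave 25.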

How the results depend on the processing

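The covariates, the fit without 3 samples and the removal of the length and GC trend were chosen after the data had been seen. All 289 called genes kept their direction under every alternative that tested them, with 276 of them tested at a filter of 100. The groups did not overlap for any of the 289. Their direction therefore could not change with samples left out, the replicate block, or another filter or variance model. Of 43 called genes named by the rule, each was called in 6 to 22 of 24 settings, and of 78 not called 23 passed in at least 1. Of 18 called lists, 10 passed in all 24 refits of the values or samples, and 12 other lists passed in at least 1. Across all settings, 346 gene results and 55 list results lost their call and 54 and 38 gained one. The count test of the plan was not run because the values are not counts, and depth is unknown, so what it limits could not be given.

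The called genes, higher, lower and changed at least 2-fold, numbered 289, 157, 132 and 5. They were 624, 322, 302 and 6 with sample quality weights and 127, 72, 55 and 12 with the liver score as a covariate. With limma 0 genes were called with the squamous and skeletal muscle score as a covariate and 0 without adrenalectomy replicate 1 and sham replicates 2 and 3, with 2301 and 1822 genes at an unadjusted p under 0.05. No other tool was run on single genes. Without a filter 104 genes were higher, with 20911 genes tested, and with the length and GC trend removed 80 were lower. At least 2-fold were 3 genes with log2 of value plus 50, 3 without a filter and 3 with robust variance. Leaving out 1 sample gave 27 to 633 genes, 14 to 349 higher, 13 to 284 lower, 0 to 10 at 2-fold and 15 to 22 lists, with 633 genes without sham replicate 1, 58 without sham replicate 2, 27 without sham replicate 3, 50 without sham replicate 4, and 86, 51, 55 and 53 without adrenalectomy replicates 1 to 4. Of the 41 lists, 18 passed in the main setting, 0 with an estimated correlation and 11 with fry. Fewer samples, or a covariate that uses up a degree of freedom, widen the test. Even so, 319 genes were called with the antral score as a covariate and 633 without sham replicate 1. These 2 fits do not show how far the width of the test accounts for the lower counts. The antral score hardly differed between the groups, and leaving out any other single sample gave 27 to 86 genes. The causes of the lower counts were not tested.

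With the replicate number as a block 4 genes were called, 3 higher, 1 lower and 1 at 2-fold. The labels do not say whether equal numbers pair the samples. The correlations of same-numbered deviations were -0.29, 0.45, -0.12 and -0.63, and number 2 alone had its own number as best partner on both sides. These deviations include RNA of neighbouring tissues that differed between single samples, so they do not settle whether the numbers pair the samples.

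A direction changed in 92 results, 89 of them past the threshold in neither setting. The 3 others, with a call in 1 setting, were the squamous list at 0.087 and the neutrophil list at 0.070 with the squamous and muscle covariate, and the cholesterol list at -0.14 without the 3 samples. Log2 differences of genes turned under quantile normalization for Muc5ac to 0.049, under median-centring for Tff1 to -0.000021 and under quality weights for Gif to 0.00055. With the liver covariate they were -0.023 for Atp4b, 0.0049 for Cftr and -0.44 for Hsd11b1. With the squamous and muscle covariate they were -0.0032 for Atp4b, 0.054 for Cd44, -0.017 for Gkn1, -0.054 for Gkn3, 0.029 for S100a8, -0.11 for Tff1 and -0.24 for Tff2. Without the 3 samples they were -0.028 for Atp4b, 0.062 for Cd44, 0.0085 for Cftr, -0.28 for Hsd11b1, 0.028 for S100a8, -0.062 for Tff1 and -0.16 for Tff2. With the length and GC trend removed they were -0.019 for Atp4b, 0.0028 for Cftr, -0.018 for Tff1 and -0.0048 for Tnf.

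For lists the direction is that of the test and the value given is the median. It turned without a filter for intestinal enterocyte genes (0.0062), at a filter of 100 for cytotoxic lymphocyte markers (-0.046), under quantile normalization for adipocyte genes (-0.023), without an intensity trend for chief cell markers (0.017), with fry for enterocyte genes (0.016), under quality weights for neuronal markers (0.014) and cholesterol genes (-0.025), and with the replicate block for adipocyte genes (-0.024) and cholesterol genes (-0.0028), beside the 4 genes called with that block. With the liver covariate it turned for chief cell markers (-0.032), enterocyte genes (0.0057) and cholesterol genes (-0.036). With the squamous and muscle covariate it also turned for surface mucous markers (-0.091), enteroendocrine markers (0.0030), enterocyte genes (0.014), adipocyte genes (0.064) and cholesterol genes (-0.067). Without the 3 samples it also turned for enteroendocrine markers (0.0052), neutrophil markers (0.033), enterocyte genes (-0.010) and adipocyte genes (0.077). With the length and GC trend removed it turned for chief cell markers (0.0036), enterocyte genes (-0.0071) and ribosomal protein genes (-0.0077).

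Leaving out 1 sample at a time gave ranges across 0, or turned the test, for Atp4b (-0.018 to 0.056), Bhlha15 (-0.041 to 0.15), Cftr (-0.12 to 0.012), Muc5ac (-0.19 to 0.017), S100a8 (-0.032 to 0.0078), Tff1 (-0.038 to 0.079), Tff2 (-0.075 to 0.21), Gif (-0.095 to 0.049) and Hsd11b1 (-0.29 to 0.66). Among lists the medians ran from -0.036 to 0.055 for chief cell, -0.028 to 0.026 for enteroendocrine, -0.084 to -0.0014 for neutrophil, -0.078 to 0.0067 for neuronal, -0.084 to 0.051 for cholesterol, -0.052 to 0.12 for adipocyte, -0.044 to -0.0084 for parietal, -0.000046 to 0.069 for intestinal enterocyte genes, -0.049 to 0.0047 for oxidative phosphorylation and -0.00020 to 0.024 for ribosomal protein genes. The causes were not tested.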

Other observations

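The genes named here that are outside the rule for named genes, those in neighbouring runs included, were chosen after their values were seen, and so was the test of neighbouring genes, while the test of symbol stems was set beforehand. Of the 289 called genes, 240 were in none of the fixed lists. Among them, Ptprc, the leukocyte common antigen CD45, rose by a log2 difference of 0.41 (adjusted p = 0.0314), Laptm5 by 0.51 (adjusted p = 0.0174), the actin regulator Coro1a by 0.42 (adjusted p = 0.0175), the adaptor gene Tyrobp by 0.33 (adjusted p = 0.0393) and Spi1, which encodes the myeloid transcription factor PU.1, by 0.26 (adjusted p = 0.0325). The heat shock protein genes Hsph1 and Hspa8 rose by 0.36 and 0.28 (adjusted p = 0.0224 each), and the stem Hspa, with 2 of 13 tested members called, did not pass a test of its share of calls (adjusted p = 1).

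The sialyltransferase gene St3gal4 rose by 0.72 (adjusted p = 0.0431), while the fucosyltransferase gene Fut4 fell by 0.81 (adjusted p = 0.0136), B4galnt2 by 0.65 (adjusted p = 0.0155) and B4galnt1 by 0.28 (adjusted p = 0.0384). Egln3, a prolyl hydroxylase induced by hypoxia, rose by 0.54 (adjusted p = 0.00834). The trefoil factor gene Tff3 fell by 0.27 (adjusted p = 0.0223), and the arginase gene Arg2 fell by 0.56 (adjusted p = 0.0467).

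Called genes lay next to each other in the genome more often than random draws of tested genes. Of 283 called genes placed in the gene order, 23 had a neighbour called in the same direction, against a median of 4 and a 95th percentile of 10 in 10000 draws (permutation p = 1e-04, the smallest these draws can give). They formed 10 runs, among them Gsdmc2, Gsdmc3 and Gsdmc4, the class II genes H2-Ab1, H2-Aa and H2-Eb1, the complement genes C1qa, C1qb and C1qc, and Oas1a with Oas1g, all higher, and Piwil4 with Fut4 and B4galnt1 with Slc26a10, lower. Most of the named higher runs are of related genes, so shared regulation, and for Gsdmc and Oas1 reads shared between paralogs, are candidate explanations for the 23 that this test does not separate. Of 540 symbol stems with at least 5 tested members, 1 held more calls than its share, H2, with 7 of 25 members called and all 7 higher (one-sided Fisher exact test, adjusted p = 7.96e-05).

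An exact permutation test of the list scores, also added after the data were seen, could not go below p = 0.0286 with 4 samples against 4, and reached it for 10 of 41 lists (adjusted p = 0.117, past no threshold). The scores of the 2 groups did not overlap for cytokine, interferon-gamma, type I interferon, antigen presentation, macrophage, dendritic cell, B cell and unfolded protein response genes, all higher after adrenalectomy, and for smooth muscle and pancreatic acinar genes, lower. Among the 35 splits of the samples, only the real one gave as small a camera p for glucocorticoid-induced, antigen presentation, B cell and unfolded protein response genes. For type I interferon genes 3 splits did, and for proliferation genes 5, skeletal muscle genes 15 and liver genes 22.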
